A study of Mus musculus with 3 samples.

How the data were processed

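Single-cell RNA was measured in cells of the infrarenal abdominal aorta of wild-type C57BL/6J mice, pooled from 5 mice per group, digested with collagenase and hyaluronidase at 37 °C and prepared with 10x Genomics Chromium 3' v2 kits. The 3 libraries were elastase day 7, elastase day 14 and heat-inactivated elastase day 14, with 1 library per group. The deposited matrices hold the authors' raw UMI counts per barcode for 27998 genes. The submitters' processing notes name Cell Ranger 3.0, Seurat 3.0 and mouse genome build mm10, and do not state how barcodes were chosen.

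The matrices held 1667 barcodes and 12014829 UMIs (heat-inactivated), 1911 and 17488592 (elastase day 7), and 1503 and 12953026 (elastase day 14). Barcodes with under 300 detected genes (168, 71 and 49) or over 10% mitochondrial UMIs (51, 27 and 19) were left out. Doublets were scored per library with Scrublet, and the highest scores were removed at a rate of 0.8% per 1000 barcodes (17, 26 and 16 cells), while its automatic threshold would have removed 8, 4 and 4. Doublets between cells of the same type, and free RNA, stay in the counts. The cells kept held 10549492, 16534549 and 12323601 UMIs.

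The 3 libraries were clustered together without integration, with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 shared nearest neighbours and Leiden resolution 1. Markers of 21 cell classes were fixed before the data were examined. The scoring rule was chosen after the clusters had been seen. It takes the mean log2 ratio of a class's markers to the median of all clusters, with values above the 0.9 quantile of a cluster capped and 10 CPM added. A class needed 3 markers that were 2-fold higher and detected in 20% of the cluster's cells. No other class was allowed more markers among the cluster's top 10 genes. Names from markers alone carry "-like".

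UMIs were summed per class and library and divided by the class's total, to give CPM. Each ratio has the exact 95% interval of a ratio of 2 Poisson counts, and each share an exact binomial one. A gene at 0 in 1 library has its ratio bounded by setting the 0 to 3 counts. No test between groups was possible with 1 library per group. The 43 gene lists, fixed with the markers, were described by the median log2 ratio of members with at least 20 UMIs over both libraries, with 0.5 added to each count and at least 5 members measured. The median was placed among 10000 random lists of the same size, drawn from 20 bins of expression. Its counting range came from 200 Poisson draws.

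Genes were named by a rule fixed with the lists. Classes with at least 50 cells in both libraries were described, up to 5 per comparison. A gene needed at least 50 UMIs and a UMI in 10% of cells where it was higher, and 20% of the level of the highest class there. Genes were ranked by the bound of the interval nearest to 1, and the top 4 in each direction (day 14 against heat-inactivated) or top 3 (other comparisons) were named. Mitochondrial, ribosomal protein, haemoglobin, Y-linked and predicted genes, Xist, and immunoglobulin and T cell receptor segments were left out. A fixed set of 24 genes was named wherever it met the minimum of 50 UMIs, as were up to 4 members of the lists described. These lists were 8 preset ones, and those outside the central 95% of random lists. Those printed were selected after the values had been seen. Coordinates, printed for the genes opening the main comparison, come from GENCODE M21 on GRCm38.

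The interval and the list percentile were tested on simulated data: Poisson counts at the depth of each comparison, with 200 genes set 2-fold or 4-fold up or down. For elastase day 14 against heat-inactivated, 8301, 4994 and 6749 genes were simulated in smooth muscle-, fibroblast- and macrophage-monocyte-like cells. There, intervals lay on the right side of 0 for 93%, 95% and 65% of 2-fold genes and 100% of 4-fold genes. For elastase day 7 against heat-inactivated, 93%, 90% and 78% of 2-fold and 100%, 100% and 94% of 4-fold genes were placed. For elastase day 14 against day 7, 100%, 97% and 99% of 2-fold genes and 100% of 4-fold genes were placed. Over all comparisons, 95.6% to 96.5% of the genes left equal were covered, as the intervals' own model was simulated. Of 40 unaltered lists per class, 0 to 5 fell outside the central 95%, and the raised and lowered lists lay at percentiles 100 and 0. The simulation holds no variation between animals or cells.

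Alternatives were a strict filter (500 genes, 5% mitochondrial), a lenient one (200 genes, 20%), no doublet removal and Scrublet's automatic threshold. Others were Leiden resolutions 0.5 and 2, separate clustering of each library, per-cell marker scores, equal weight for each cell, median-of-ratios scaling, free RNA subtracted at 5% of each class's UMIs, and list minimums of 1 UMI in each library or 100 UMIs. Classes with under 20 cells in either library gave no ratios. Sequence reads were not used here, and 1 list member is not reported here.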

Results

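Single-cell RNA sequencing was used to profile the infrarenal abdominal aorta of C57BL/6J mice at day 7 and day 14 after elastase was applied around the vessel, and at day 14 after heat-inactivated elastase. Each of the 3 libraries held the cells of 1 pool of 5 mice. The spread between animals could therefore not be measured, no test between groups was made, and all intervals are exact 95% intervals that cover counting error only. The heat-inactivated library was the comparator of both elastase libraries. Elastase day 7 had no heat-inactivated partner of its own day, so that day and treatment both differ in that comparison. After filtering, 4639 cells were kept, 1432 from the heat-inactivated library, 1787 from elastase day 7 and 1420 from elastase day 14, with medians of 7043, 8141 and 7809.5 UMIs per cell. Medians differed more in fibroblast-like (5174, 14642.5 and 9477.5) and macrophage-monocyte-like cells (4402.5, 7951.5 and 7901). The median mitochondrial share of UMIs was 4.39%, 2.32% and 2.59%, in the same order. Joint clustering gave 24 clusters, and each was assigned to the class whose marker genes it expressed most.

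Elastase libraries held more macrophage-monocyte-like cells and fewer smooth muscle-like cells than the heat-inactivated library. Macrophage-monocyte-like cells made up 10.3% [8.81, 12.03] of the heat-inactivated library, 43.9% [41.6, 46.2] of elastase day 7 and 42.9% [40.3, 45.5] of elastase day 14. The shares of smooth muscle-like cells were 49.2% [46.5, 51.8], 14.9% [13.3, 16.6] and 18.0% [16.1, 20.1]. With a stricter filter, which removes many smooth muscle-like cells through their mitochondrial RNA (medians of 5.47%, 5.39% and 5.10%), these shares were 27.6%, 5.83% and 9.83%. Fibroblast-like cells accounted for 21.2% [19.1, 23.4], 16.0% [14.3, 17.8] and 14.1% [12.3, 16.0]. The strict filter moved the heat-inactivated shares of macrophage-monocyte- and fibroblast-like cells to 16.5% and 32.0%.

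Lymphocytes and dendritic cells also differed in share. T cell-like cells were 3.003% [2.18, 4.02] of the heat-inactivated library, 9.18% [7.88, 10.6] of elastase day 7 and 9.65% [8.16, 11.3] of elastase day 14. The corresponding values for dendritic-like cells were 0.978% [0.536, 1.63], 7.00% [5.86, 8.28] and 6.06% [4.87, 7.43]. Natural killer (NK) cell-like cells had a higher share at elastase day 7 (4.70% [3.77, 5.79]) than at elastase day 14 (1.13% [0.645, 1.82]) or in the heat-inactivated library (0.559% [0.242, 1.10]). B cell-like cells made up 3.84% [2.91, 4.97], 1.90% [1.32, 2.65] and 2.39% [1.66, 3.33]. Endothelial-like cells were 5.38% [4.27, 6.67], 1.12% [0.685, 1.72] and 2.39% [1.66, 3.33], and Schwann-neural-like cells 0.768% [0.384, 1.37], 0.616% [0.308, 1.10] and 1.55% [0.973, 2.34]. Lymphatic endothelial-like cells numbered 13 in the heat-inactivated library and 1 in each elastase library (0.908% [0.484, 1.55], 0.0560% [0.00140, 0.311] and 0.0704% [0.00180, 0.392]). Erythroid-like cells, which depend on the blood left in the tissue, were 3.91% [2.97, 5.05], 0.672% [0.347, 1.17] and 1.76% [1.14, 2.59]. With the lenient filter they were 10.3%, 2.13% and 3.36%, and with the strict filter 0%. The heat-inactivated dendritic-like share was 2.35% with the strict filter, 2.03% at resolution 0.5 and 0% with separate clustering. Separate clustering also gave 6.15% for B cell-like cells there, and 0% for lymphatic endothelial-like cells in each library and for NK cell-like cells in both day 14 libraries. Per-cell marker scores gave NK cell-like shares of 6.72% and 2.32% at elastase days 7 and 14.

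**Figure D1:**
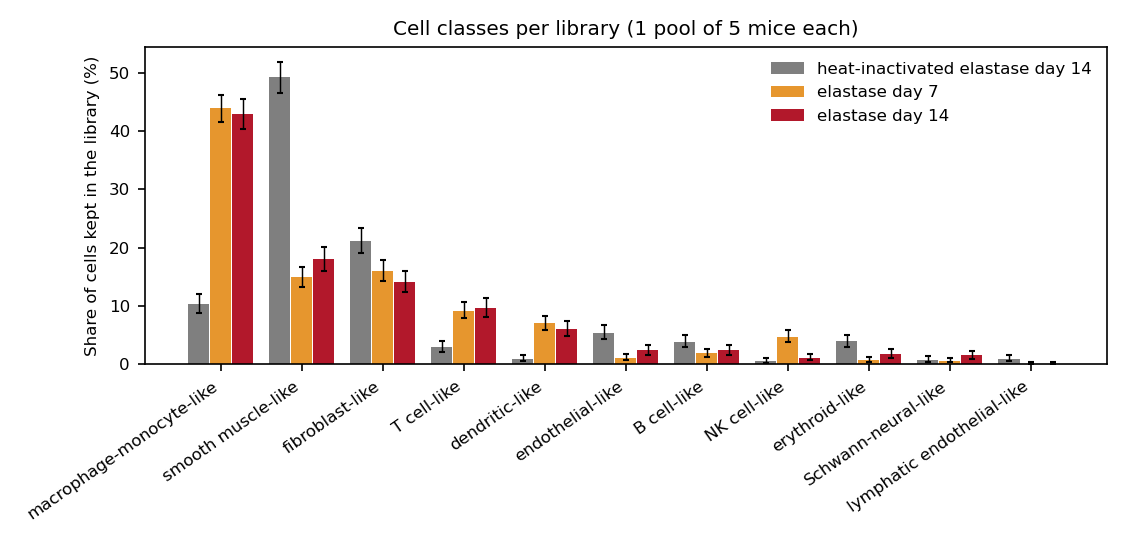
Share of each cell class (vertical axis, percent of the cells kept) in the heat-inactivated elastase day 14, elastase day 7 and elastase day 14 libraries (bar colours). Error bars are exact binomial 95% intervals and cover counting error only.

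Elastase day 14 was compared with heat-inactivated elastase at the same day within the 3 largest classes. Heat shock genes were higher in smooth muscle-like cells of the elastase library, led by the inducible Hsp70 genes Hspa1b (12.9-fold [11.8, 14.1]) and Hspa1a (6.29-fold [6.01, 6.58]). Contractile genes had a median close to 0 there, and Eln, which encodes elastin, was lower (log2 -0.37 [-0.42, -0.33]). In fibroblast-like cells, the acute phase gene Saa3 was 223-fold [135, 399.6] higher, and chemokine and interferon response genes were higher as groups. Resident macrophage genes were lower and proliferation genes higher (medians -2.84 and 1.70) in macrophage-monocyte-like cells of the elastase library, which lay in other clusters. Clusters 6 and 9, weighted equally, gave -0.35 and -0.0068, but leave out cluster 18, marked by the histone gene Hist1h2ap (33 and 1 cells).

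In smooth muscle-like cells (256 cells of elastase day 14 and 704 of the heat-inactivated library), gene levels are given as counts of UMIs scaled to the class total (CPM). Each pair holds the elastase library and then the heat-inactivated library, followed by the log2 ratio with its interval. The leading higher genes were Hspa1b (1264 and 98.1, 3.69 [3.56, 3.82]) and Hspa1a (2673 and 425, 2.65 [2.59, 2.72]), with the cochaperone Dnajb1 (864 and 188, 2.20 [2.10, 2.31]) and the Hsp110 gene Hsph1 (243 and 73.2, 1.73 [1.56, 1.91]). Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain. Lower genes were Ccl21a (2.49 and 15.1, -2.60 [-4.08, -1.42]), a chemokine of lymphatic endothelial-like cells (1 and 13 cells), Ppm1n (18.7 and 65.5, -1.81 [-2.29, -1.36]), the circadian transcription factor Dbp (16.6 and 48.6, -1.55 [-2.06, -1.07]) and the antisense transcript Hoxd3os1 (17.0 and 41.5, -1.29 [-1.80, -0.81]). Subtracting free RNA, at 5% of each class's UMIs, turned the Ccl21a ratio to 1.35.

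Gene groups are described by the number of measured members that were higher in the elastase library and by their median log2 ratio, which lay outside the central 95% of 10000 random lists of similar expression unless a percentile is given. Every heat shock member was higher in smooth muscle-like cells (12 of 12, 1.43). Contractile genes were split evenly (12 of 24, -0.00170, percentile 83.3), with Acta2 (17753 and 16201, 0.13 [0.12, 0.15]) and Myh11 (2482 and 2446, 0.02 [-0.02, 0.06]) among them. Further contractile genes were Tagln (15499 and 14814, 0.07 [0.05, 0.08]), Cnn1 (1551 and 1359, 0.19 [0.13, 0.25]) and Pln (38.6 and 18.1, 1.09 [0.68, 1.50]), the last of which regulates the sarcoplasmic calcium pump. The strict filter turned Acta2 to -0.02 and Tagln to -0.07. Among groups of the stress response were unfolded protein response (15 of 16, 0.37), immediate early genes (14 of 19, 0.16) and cell death genes (8 of 13, 0.23). Sterol genes (cholesterol synthesis (12 of 15, 0.43)) included the mevalonate pathway gene Idi1 (32.0 and 16.2, 0.98 [0.54, 1.42]). For the Notch pathway (6 of 10, 0.24), the target gene Nrarp (32.0 and 3.78, 3.08 [2.41, 3.81]) was higher, and the median was -0.06 with smooth muscle-like clusters weighted equally.

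Elastic fibre genes of smooth muscle-like cells were lower as a group at elastase day 14. The elastic fibre group (4 of 17, -0.22) held Eln (1954 and 2529, -0.37 [-0.42, -0.33]), Fbn1 (104 and 121, -0.22 [-0.43, -0.01]) and Lox (201 and 209, -0.06 [-0.21, 0.10]), which encode elastin, fibrillin-1 and lysyl oxidase, and Mfap2 (18.3 and 26.9, -0.56 [-1.07, -0.07]) and Ltbp2 (23.3 and 14.5, 0.68 [0.18, 1.18]). The strict filter turned Fbn1 to 0.10. None of the fibrillar collagens was higher (0 of 5, -0.13, percentile 12.1), with Col1a1 (775 and 904, -0.22 [-0.30, -0.15]) and Col3a1 (1666 and 1892, -0.18 [-0.24, -0.13]). For collagen-modifying enzymes (collagen processing (11 of 15, 0.13)), the prolyl hydroxylase P4ha1 (54.4 and 31.3, 0.80 [0.47, 1.12]) was higher. Matrix metalloproteinases (2 of 6, -0.12, percentile 27.9) included Mmp2 (25.8 and 24.4, 0.08 [-0.37, 0.51]) and Mmp3 (17.9 and 9.60, 0.90 [0.30, 1.48]), at 3.03% and 1.63% of the highest class. The matricellular gene Thbs1 (281 and 119, 1.23 [1.08, 1.38]) was higher, while Tnc (156 and 170.4, -0.13 [-0.30, 0.04]), Tgfb1 (47.8 and 46.9, 0.03 [-0.30, 0.34]) and Klf4 (514 and 548, -0.09 [-0.19, 0.00370]) differed little.

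Leukocyte and inflammatory groups were mostly higher in smooth muscle-like cells but lay far below the highest class. The chemokines (13 of 16, 0.79) had a median level of 3.52% of that in the highest class, and MHC class II genes (6 of 6, 1.97) one of 2.18%. At 2 to 14% of the highest class were also inflammatory cytokines and mediators (9 of 11, 0.53), interferon response (13 of 18, 0.35), MHC class I (7 of 12, 0.23) and complement (11 of 13, 1.23). The same held for inflammatory macrophage (11 of 12, 1.76), lipid-associated macrophage (12 of 15, 0.37) and classical monocyte (6 of 8, 1.06). Genes at such levels were Il1b (35.3 and 2.68, 3.72 [2.96, 4.57]), Il6 (39.5 and 38.2, 0.05 [-0.31, 0.39]), Ccl2 (49.4 and 27.7, 0.84 [0.49, 1.18]), Timp1 (35.7 and 13.4, 1.42 [0.97, 1.87]), Vcam1 (20.4 and 18.3, 0.16 [-0.36, 0.65]) and Icam1 (6.65 and 10.2, -0.62 [-1.51, 0.18]). Subtracting free RNA turned Ccl2 to -0.30, and the interferon response and MHC class I medians to -0.03 and -0.33. Remaining groups were proliferation (4 of 7, 0.13, percentile 73.4) and endothelial lipid uptake (6 of 8, 0.31).

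Fibroblast-like cells (200 and 303 cells) showed the largest ratios of single genes. Higher genes were Saa3 (2047 and 9.16, 7.80 [7.08, 8.64]), Chl1 (92.2 and 0, at least 50.3-fold), which encodes a neural adhesion molecule, osteopontin Spp1 (173 and 1.83, 6.56 [5.01, 8.85], 3 UMIs in the latter) and the siderophore-binding gene Lcn2 (106 and 0.611, 7.44 [4.95, 12.75], 1 UMI in the latter). Lower genes were the bicarbonate transporter Slc4a10 (12.6 and 92.2, -2.87 [-3.49, -2.30]), the neurotrophin Ntf3 (7.55 and 56.2, -2.90 [-3.71, -2.16]), the sphingomyelinase Smpd3 (23.1 and 129, -2.49 [-2.94, -2.06]) and the methyltransferase Inmt (41.1 and 210.1, -2.35 [-2.69, -2.03]). Clusters 4 and 11 held most fibroblast-like cells of the heat-inactivated library (213 and 84 of 303), whereas cluster 5, with median UMIs of 16475 per cell, held 88 of 200 at elastase day 14 and 6 in the heat-inactivated library.

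Inflammatory groups were higher in fibroblast-like cells: chemokines (18 of 20, 1.78), inflammatory cytokines and mediators (12 of 14, 1.25) and interferon response (21 of 22, 1.11). Their members included the neutrophil chemokine Cxcl5 (91.8 and 0, at least 50.1-fold), the B cell chemokine Cxcl13 (70.8 and 1.83, 5.27 [3.70, 7.57], 3 UMIs in the latter) and the interferon regulator Irf7 (188 and 33.0, 2.51 [2.10, 2.94]). Other such genes were Ccl2 (989.7 and 323, 1.62 [1.48, 1.75]), Il6 (339 and 446, -0.39 [-0.54, -0.25]) and Il1b (35.6 and 1.22, 4.87 [2.97, 7.94], 2 UMIs in the latter), with Il1b at 2.79% of the highest class. With clusters 4 and 11 weighted equally, the chemokine median was 0.90. Adhesion molecules (leukocyte adhesion molecules (5 of 7, 1.30)) held Vcam1 (416 and 91.6, 2.18 [1.93, 2.44]) and Icam1 (148 and 198, -0.42 [-0.64, -0.19]), and their median was -0.29 with clusters weighted equally. Antigen presentation and innate groups were MHC class I (11 of 12, 0.46), MHC class II (6 of 6, 1.93), complement (10 of 15, 0.47) and inflammatory macrophage (9 of 10, 2.09), of which MHC class II lay at 2.08% of the highest class.

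Several matrix remodelling genes were also higher in fibroblast-like cells. Matricellular genes (matricellular and wound matrix (12 of 15, 0.97)) included Thbs1 (638 and 33.6, 4.25 [3.86, 4.66]) and Tnc (83.8 and 8.55, 3.29 [2.51, 4.19]). Of the matrix metalloproteinases (6 of 8, 0.59), the collagenase Mmp13 (32.7 and 0, at least 17.8-fold) was higher, beside Mmp3 (1095 and 848, 0.37 [0.27, 0.46]) and Mmp2 (849.7 and 949, -0.16 [-0.26, -0.06]). The inhibitor Timp1 (1175 and 217, 2.43 [2.27, 2.60]) and the cytokine Tgfb1 (67.9 and 33.0, 1.04 [0.59, 1.51]) were higher. Elastic fibre genes (12 of 19, 0.15, percentile 77.6) included Eln (1636 and 1218, 0.43 [0.35, 0.50]), Fbn1 (663 and 448, 0.57 [0.44, 0.69]) and Lox (519 and 483, 0.10 [-0.03, 0.23]). Fibrillar collagens (3 of 7, -0.04, percentile 28.4) were led by Col11a1 (44.9 and 3.66, 3.61 [2.44, 5.09]), Col1a1 (17465 and 23142, -0.41 [-0.43, -0.39]) and Col3a1 (19719.6 and 24032, -0.29 [-0.30, -0.27]). Weighting each cell equally turned Mmp3 to -0.06.

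Stress and metabolic groups of fibroblast-like cells were heat shock (12 of 12, 1.27), glycolysis (14 of 15, 0.42), hypoxia (9 of 11, 0.45) and cytosolic ribosomal proteins (21 of 22, 0.32). Immediate early genes were mostly lower (5 of 19, -0.48), among them Junb (1638 and 3721, -1.18 [-1.24, -1.13]) and Klf4 (2199 and 3285, -0.58 [-0.63, -0.52]). Cytoskeletal and proliferation groups were actin remodelling and motility (17 of 20, 0.47) and proliferation (7 of 7, 1.48). Smooth muscle genes lay at 2 to 6% of the highest class, and the contractile group (10 of 20, -0.05, percentile 21.9) included Acta2 (432 and 428, 0.01 [-0.13, 0.15]), Myh11 (45.7 and 63.5, -0.48 [-0.88, -0.07]), Tagln (572 and 305, 0.91 [0.76, 1.06]) and Cnn1 (41.5 and 48.2, -0.22 [-0.66, 0.23]). Subtracting free RNA turned Myh11 to 3.47. Groups shared with myeloid cells were classical monocyte (7 of 7, 1.61) and lipid-associated macrophage (9 of 15, 0.44). The lipid-associated median was -0.10 at a minimum of 100 UMIs.

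Macrophage-monocyte-like cells (609 and 148 cells) were held mostly by cluster 6 in the heat-inactivated library (100 cells) and by clusters 1, 2, 9 and 10 at elastase day 14 (274, 67, 95 and 81 cells). Higher genes were AA467197 (304 and 5.65, 5.75 [4.39, 7.63]), Cd72 (997 and 41.0, 4.61 [4.08, 5.19]), which encodes a C-type lectin and also marked cluster 1, the arginine synthesis gene Ass1 (108 and 1.41, 6.26 [3.78, 11.57], 1 UMI in the latter) and the inhibitory receptor Cd300lf (57.4 and 0, at least 13.5-fold). The chemokine Ccl24 (11.9 and 298, -4.65 [-5.08, -4.24]), the alternative activation gene Retnla (51.5 and 980.3, -4.25 [-4.46, -4.05]), which also marked cluster 20, the gelatinase Mmp9 (7.84 and 151, -4.27 [-4.82, -3.74]) and the cytokine Tslp (5.17 and 87.6, -4.08 [-4.79, -3.41]) were lower. Leiden clustering at resolution 0.5 gave 4.53 for Ass1 and -6.63 for Retnla.

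Resident macrophage genes (1 of 14, -2.84) included the scavenger receptor Cd163 (7.65 and 100.3, -3.71 [-4.31, -3.13]) and F13a1 (62.2 and 476, -2.94 [-3.16, -2.71]). Proliferation genes were higher over all cells (21 of 22, 1.70, and 1.40 with genes at 0 set to 3 counts) and included Mki67 (20.3 and 1.41, 3.84 [1.33, 9.16], 1 UMI in the latter) and Birc5 (36.9 and 2.82, 3.71 [1.84, 6.76], 2 UMIs in the latter). Also higher were interferon response (17 of 23, 0.83), heat shock (11 of 12, 0.76), glycolysis (12 of 15, 0.52), cell death genes (11 of 16, 0.59) and actin remodelling and motility (17 of 20, 0.52), with Irf7 (524 and 83.3, 2.65 [2.28, 3.05]) and Slc2a1 (32.5 and 7.06, 2.20 [0.95, 3.84]) among their members. Lower groups were immediate early genes (1 of 19, -0.89), alternatively activated macrophage (4 of 13, -0.56), lipid-associated macrophage (5 of 16, -0.52) and lysosomal cathepsins (3 of 10, -0.52). With clusters 6 and 9 alone weighted equally, the medians of the cell death, lipid-associated and cathepsin groups were -0.00110, 0.09 and 0.14.

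Inflammatory genes of macrophage-monocyte-like cells went in both directions. The interleukin Il1b (728 and 154, 2.24 [1.97, 2.53]) was higher, while Ccl2 (1300.5 and 3836, -1.56 [-1.63, -1.50]), Il6 (11.7 and 31.1, -1.41 [-2.14, -0.64]) and Icam1 (78.6 and 168, -1.10 [-1.39, -0.79]) were lower. Groups without a shared direction were chemokines (8 of 18, -0.13, percentile 10.4), inflammatory cytokines and mediators (6 of 14, -0.17, percentile 13.4) and matrix metalloproteinases (4 of 8, -0.09, percentile 30.2). Higher also were Spp1 (305 and 109, 1.49 [1.16, 1.84]), Thbs1 (369 and 107, 1.78 [1.45, 2.13]) and Tgfb1 (371 and 321, 0.21 [0.01, 0.42]), and Klf4 (277 and 874, -1.66 [-1.79, -1.52]) and Vcam1 (14.3 and 56.5, -1.98 [-2.55, -1.39]) were lower. Further lower groups were ADAM and ADAMTS proteases (2 of 8, -0.72), Notch pathway (0 of 5, -0.99), phenotype regulators of smooth muscle (4 of 10, -0.59), endothelial lipid uptake (2 of 7, -1.15) and endothelial identity (1 of 8, -0.89), the last 3 at 9 to 33% of the highest class, with fewer smooth muscle- and endothelial-like cells in that library.

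Genes of the aortic wall were mostly lower in macrophage-monocyte-like cells of the elastase library and lay at low levels there. The contractile group (2 of 20, -1.48) had a median level of 3.87% of the highest class, and smooth muscle-like cells were more numerous in the heat-inactivated library. Its members included Acta2 (193 and 524, -1.44 [-1.62, -1.27]), Myh11 (23.9 and 73.4, -1.62 [-2.10, -1.12]), Tagln (109 and 302, -1.47 [-1.70, -1.24]) and Cnn1 (20.7 and 74.9, -1.86 [-2.34, -1.35]). Matrix groups at 1 to 7% of the highest class were elastic fibre (5 of 17, -0.92), fibrillar collagens (0 of 5, -0.38, percentile 11.2), basement membrane (0 of 12, -1.08), matricellular and wound matrix (3 of 11, -0.65) and heritable aortic aneurysm genes (7 of 21, -0.48). Matrix genes among them were Eln (41.9 and 102, -1.28 [-1.67, -0.87]), Fbn1 (14.0 and 8.47, 0.72 [-0.47, 2.21]), Col1a1 (128 and 164, -0.36 [-0.65, -0.06]) and Col3a1 (227 and 299, -0.40 [-0.61, -0.18]), beside Mmp2 (14.3 and 4.24, 1.76 [0.16, 4.07], 3 UMIs in the latter), Mmp3 (17.4 and 14.1, 0.30 [-0.64, 1.41]) and Timp1 (23.9 and 18.4, 0.38 [-0.45, 1.33]). Weighting clusters 6 and 9 alone equally gave a matricellular median of 0.01.

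On GRCm38, the genes that open this comparison are Hspa1b (chr17, 34956436 to 34959238), Hspa1a (chr17, 34969190 to 34972156), Eln (chr5, 134702593 to 134747323) and Saa3 (chr7, 46711998 to 46715700).

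**Figure D2:**
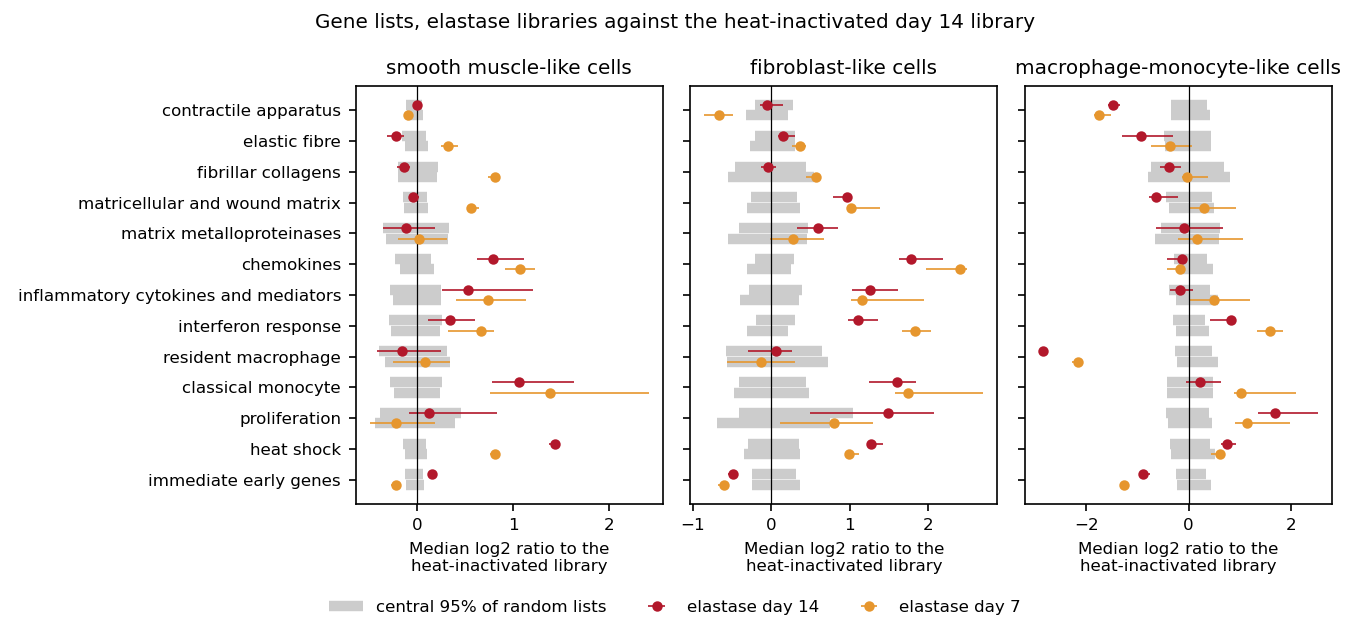
Median log2 ratio (horizontal axis) of each gene group (vertical axis) in elastase day 14 and elastase day 7 against the heat-inactivated library, in smooth muscle-like, fibroblast-like and macrophage-monocyte-like cells. Horizontal lines give the counting range and grey bars the central 95% of random lists of similar expression.

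Elastase day 7 differed from the heat-inactivated library in matrix genes of smooth muscle-like cells. Eln was 2.08-fold [2.03, 2.12] higher and all measured fibrillar collagens were higher, beside Igfbp2, a binding protein of insulin-like growth factors (9.25-fold [7.47, 11.5]). Heat shock genes were higher in this library too. In fibroblast-like cells, Saa3 (189-fold [114, 337]) and the complement factor Cfd (122-fold [76.4, 210.2]) were higher, and chemokine and interferon response genes were higher as groups. Resident macrophage genes were lower, and interferon response and classical monocyte genes higher, in macrophage-monocyte-like cells, which lay in other clusters (medians of -2.17, 1.60 and 1.03, against -0.16, 0.74 and 0.16 with clusters 6 and 9 weighted equally).

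In smooth muscle-like cells (266 and 704 cells), the leading higher genes were Igfbp2 (156 and 16.8, 3.21 [2.90, 3.53]), Hspa1b (542 and 98.1, 2.47 [2.33, 2.60]) and Hspa1a (1316 and 425, 1.63 [1.56, 1.70]). Lower genes were Sbno2 (7.90 and 23.6, -1.58 [-2.30, -0.93]), the neurotrophin Ntf3 (43.8 and 96.3, -1.14 [-1.43, -0.85]) and the cold-inducible RNA-binding gene Cirbp (94.4 and 184, -0.97 [-1.16, -0.77]). Matrix groups were higher: fibrillar collagens (5 of 5, 0.81), elastic fibre (12 of 17, 0.33), collagen processing (15 of 15, 0.34), matricellular and wound matrix (13 of 14, 0.56) and basement membrane (10 of 13, 0.24). Their genes included Eln (5253 and 2529, 1.05 [1.02, 1.09]), Fbn1 (150.1 and 121, 0.31 [0.13, 0.48]) and Lox (295 and 209, 0.49 [0.37, 0.62]), Col1a1 (1677 and 904, 0.89 [0.83, 0.95]), Col3a1 (2957 and 1892, 0.64 [0.60, 0.68]) and Postn (1472 and 729, 1.01 [0.95, 1.07]), and Tnc (249 and 170.4, 0.55 [0.41, 0.69]), Thbs1 (199.6 and 119, 0.74 [0.58, 0.90]) and Sparc (6235 and 3367, 0.89 [0.86, 0.92]). Col1a1 lay at 7.74% and Col3a1 at 10.8% of their level in fibroblast-like cells, and Col5a1 and Col5a2 at higher percentages. Proteoglycan genes had a negative median (proteoglycans and cartilage matrix (6 of 13, -0.29)), which was 0.28 with the strict filter.

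Contractile genes of smooth muscle-like cells had a median of -0.09 (6 of 24 higher, percentile 4.54), with Acta2 (16731 and 16201, 0.05 [0.03, 0.06]), Myh11 (2222 and 2446, -0.14 [-0.18, -0.10]), Tagln (14169 and 14814, -0.06 [-0.08, -0.05]) and Cnn1 (1595 and 1359, 0.23 [0.18, 0.28]). Calcium handling gene Pln (8.62 and 18.1, -1.07 [-1.77, -0.43]) was lower. Stress groups were heat shock (12 of 12, 0.81), unfolded protein response (17 of 17, 0.39) and immediate early genes (4 of 19, -0.22), the last with Nr4a1 (518 and 814, -0.65 [-0.74, -0.57]). The strict filter turned the immediate early median to 0.03 and Klf4 (469.9 and 548, -0.22 [-0.31, -0.13]) to 0.22. Other groups were actin remodelling and motility (15 of 20, 0.18), lysosomal cathepsins (9 of 10, 0.26) and angiogenic tip endothelium (4 of 6, 0.31). Protease and growth groups were matrix metalloproteinases (3 of 6, 0.03, percentile 59.5) and proliferation (1 of 6, -0.21, percentile 18.0). Mmp2 (47.7 and 24.4, 0.97 [0.62, 1.31]), Mmp3 (12.6 and 9.60, 0.39 [-0.25, 1.01]) and Tgfb1 (64.6 and 46.9, 0.46 [0.19, 0.73]) lay at 5.76%, 1.38% and 5.44% of the highest class. With the strict filter Acta2 was -0.09, and a list minimum of 1 UMI gave -0.25 for tip endothelium.

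Leukocyte genes in smooth muscle-like cells again lay at 1 to 8% of the highest class. Groups were chemokines (13 of 16, 1.07), inflammatory cytokines and mediators (7 of 10, 0.74), interferon response (14 of 18, 0.67), MHC class II (6 of 6, 1.56) and MHC class I (9 of 12, 0.26). Myeloid groups were complement (11 of 13, 0.45), inflammatory macrophage (8 of 10, 1.55), lipid-associated macrophage (9 of 15, 0.32) and classical monocyte (9 of 9, 1.39). Genes at these levels were Il1b (21.2 and 2.68, 2.98 [2.19, 3.86]), Ccl2 (58.9 and 27.7, 1.09 [0.77, 1.40]), Spp1 (24.1 and 1.42, 4.09 [3.08, 5.28]) and Timp1 (21.9 and 13.4, 0.71 [0.21, 1.20]), with Il1b at 1.44%. Vcam1 (47.4 and 18.3, 1.38 [1.01, 1.75]) was higher, Il6 (18.7 and 38.2, -1.03 [-1.50, -0.60]) lower and Icam1 (10.8 and 10.2, 0.07 [-0.60, 0.72]) near 0. Subtracting free RNA turned Ccl2 to -0.61, Timp1 to -0.17, and the cytokine and interferon response medians to -0.34 and -0.29. It turned the MHC class I median to -0.29, and the strict filter turned Il6 to 0.11.

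Fibroblast-like cells at elastase day 7 (286 cells, 185 of them in cluster 5) had higher Saa3 (1727 and 9.16, 7.56 [6.84, 8.40]), Cfd (1270.2 and 10.4, 6.94 [6.25, 7.72]) and Cxcl5 (101 and 0, at least 55.3-fold). Lower genes were Inmt (11.7 and 210.1, -4.17 [-4.63, -3.74]) and Ntf3 (4.91 and 56.2, -3.52 [-4.28, -2.82]) and the actin-severing gene Gsn (1754 and 11514, -2.71 [-2.75, -2.68]). Classes taken from per-cell marker scores, where Cfd is an adipocyte marker, gave 2.81 for Cfd. Inflammatory groups were chemokines (19 of 21, 2.41), interferon response (22 of 23, 1.83), inflammatory cytokines and mediators (13 of 15, 1.16) and leukocyte adhesion molecules (4 of 6, 0.63). Their genes included Cxcl13 (171 and 1.83, 6.55 [4.99, 8.83], 3 UMIs in the latter), Cxcl9 (106 and 6.72, 3.98 [3.13, 4.99]) and Lcn2 (54.5 and 0.611, 6.48 [3.99, 11.79], 1 UMI in the latter), Ccl2 (1720.3 and 323, 2.41 [2.29, 2.54]), Il6 (382 and 446, -0.22 [-0.35, -0.09]) and Il1b (26.4 and 1.22, 4.44 [2.55, 7.498], 2 UMIs in the latter), and Vcam1 (321 and 91.6, 1.81 [1.57, 2.06]) and Icam1 (147 and 198, -0.43 [-0.62, -0.23]). With clusters 4 and 11 weighted equally, the chemokine median was 1.30. Groups of innate immunity were complement (9 of 15, 0.57), MHC class I (11 of 12, 0.35), MHC class II (6 of 6, 1.88) and inflammatory macrophage (12 of 13, 2.46). The adhesion median was -0.43 with a list minimum of 1 UMI.

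Matrix groups of fibroblast-like cells were matricellular and wound matrix (12 of 15, 1.01), elastic fibre (14 of 19, 0.36), fibrillar collagens (5 of 7, 0.57) and matrix metalloproteinases (6 of 8, 0.27, percentile 88.3). They held Eln (3461 and 1218, 1.51 [1.44, 1.57]), Fbn1 (703 and 448, 0.65 [0.53, 0.77]) and Lox (748 and 483, 0.63 [0.52, 0.74]), Thbs1 (279.9 and 33.6, 3.06 [2.67, 3.48]), Tnc (47.5 and 8.55, 2.47 [1.69, 3.37]) and Spp1 (159 and 1.83, 6.44 [4.88, 8.72], 3 UMIs in the latter), and Col1a1 (21662 and 23142, -0.10 [-0.11, -0.08]), Col3a1 (27408 and 24032, 0.19 [0.17, 0.21]), Mmp2 (829 and 949, -0.19 [-0.28, -0.11]) and Mmp3 (908 and 848, 0.10 [0.01, 0.19]). Timp1 (821 and 217, 1.92 [1.76, 2.08]) and Tgfb1 (44.9 and 33.0, 0.45 [0.00270, 0.91]) were higher. Lower groups were basement membrane (3 of 15, -0.54) and immediate early genes (4 of 19, -0.60), the latter with Fos (2439 and 6849, -1.49 [-1.53, -1.45]) and Klf4 (2348 and 3285, -0.48 [-0.53, -0.44]). Smooth muscle genes lay at 2 to 5% of the highest class (contractile apparatus (4 of 20, -0.66)), with Acta2 (238 and 428, -0.84 [-0.98, -0.70]), Myh11 (22.4 and 63.5, -1.50 [-1.92, -1.09]), Tagln (229 and 305, -0.41 [-0.57, -0.26]) and Cnn1 (20.6 and 48.2, -1.23 [-1.68, -0.77]). Subtracting free RNA turned the contractile median to 0.43. Cnn1 was then 0.04. No Acta2, Myh11 or Tagln was left in the heat-inactivated library. Their values of 5.61, 0.65 and 5.83 rest on the 3 counts set there and do not measure a rise. Weighting each cell equally turned Mmp3 to -0.13, and median-of-ratios scaling turned Col1a1 to 0.00320.

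Other groups higher in fibroblast-like cells were heat shock (12 of 12, 0.99), unfolded protein response (17 of 18, 0.44), hypoxia (8 of 12, 0.42) and cholesterol synthesis (10 of 12, 0.65). The same direction was seen for cytosolic ribosomal proteins (22 of 22, 0.52), actin remodelling and motility (16 of 20, 0.35) and proliferation (5 of 6, 0.80), of which proliferation had a median of -0.04 without doublet removal. Myeloid groups were classical monocyte (9 of 9, 1.75) and lipid-associated macrophage (10 of 16, 0.63). The lipid-associated median was -0.33 with per-cell marker scores, and the complement median -0.12 with free RNA subtracted.

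Macrophage-monocyte-like cells at elastase day 7 (784 cells, with 295 in cluster 2, 190 in cluster 1 and 87 in cluster 6) had higher AA467197 (528 and 5.65, 6.55 [5.19, 8.42]), Ass1 (169.8 and 1.41, 6.91 [4.43, 12.21], 1 UMI in the latter) and Cd300lf (82.8 and 0, at least 19.5-fold). Lower genes were Retnla (31.9 and 980.3, -4.94 [-5.17, -4.72]) and Ccl24 (20.4 and 298, -3.87 [-4.19, -3.55]) and the lectin Mgl2 (32.3 and 407, -3.65 [-3.92, -3.39]). Resident macrophage genes were lower (1 of 14, -2.17), among them Pf4 (445 and 2771, -2.64 [-2.72, -2.55]), and higher groups were interferon response (22 of 23, 1.60), classical monocyte (10 of 12, 1.03), proliferation (19 of 22, 1.15) and glycolysis (12 of 15, 0.95). Their genes included Irf7 (1058 and 83.3, 3.67 [3.30, 4.06]), Ly6c2 (784 and 66.4, 3.56 [3.15, 4.01]), Chil3 (30.4 and 1.41, 4.43 [1.93, 9.74], 1 UMI in the latter) and Mki67 (11.6 and 1.41, 3.04 [0.52, 8.36], 1 UMI in the latter), of which Ly6c2 also marked cluster 2. With clusters 6 and 9 alone weighted equally, the proliferation median was -0.28.

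Further groups of macrophage-monocyte-like cells were MHC class I (12 of 12, 0.59), heat shock (9 of 12, 0.62), actin remodelling and motility (18 of 20, 0.67), immediate early genes (1 of 19, -1.26) and lipid-associated macrophage (5 of 16, -0.32). Without a shared direction were chemokines (9 of 20, -0.17, percentile 3.79), inflammatory cytokines and mediators (11 of 17, 0.49, percentile 93.3) and matrix metalloproteinases (5 of 8, 0.17, percentile 72.5). Higher genes were Il1b (672 and 154, 2.13 [1.85, 2.41]), Spp1 (662 and 109, 2.61 [2.28, 2.95]), Thbs1 (621 and 107, 2.53 [2.21, 2.88]) and Tgfb1 (369.8 and 321, 0.21 [0.01, 0.41]). Lower were Ccl2 (1409.6 and 3836, -1.44 [-1.51, -1.38]), Il6 (12.4 and 31.1, -1.33 [-2.02, -0.58]) and Mmp9 (45.3 and 151, -1.74 [-2.06, -1.41]) and Klf4 (281 and 874, -1.64 [-1.77, -1.50]), Vcam1 (25.3 and 56.5, -1.16 [-1.66, -0.62]) and Icam1 (78.4 and 168, -1.10 [-1.39, -0.80]). The strict filter moved Mmp9 to -4.11. Lower groups were ADAM and ADAMTS proteases (2 of 8, -0.54), Notch pathway (1 of 5, -0.97), phenotype regulators of smooth muscle (3 of 10, -0.77), endothelial identity (2 of 9, -0.89) and endothelial lipid uptake (2 of 7, -1.48), the last 3 at 27 to 33% of the highest class, again beside fewer such cells. With clusters weighted equally, the lipid-associated median was 0.37.

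Aortic wall genes in these macrophage-monocyte-like cells were again at low levels, the contractile group at 4.13% of the highest class (contractile apparatus (1 of 21, -1.74)) with Acta2 (157 and 524, -1.74 [-1.91, -1.57]), Myh11 (20.1 and 73.4, -1.87 [-2.34, -1.38]), Tagln (84.8 and 302, -1.83 [-2.06, -1.60]) and Cnn1 (16.8 and 74.9, -2.16 [-2.64, -1.66]). Matrix groups were fibrillar collagens (2 of 5, -0.03, percentile 40.7), elastic fibre (7 of 17, -0.36, percentile 6.32) and basement membrane (0 of 11, -0.99). Single genes were Eln (119 and 102, 0.22 [-0.13, 0.59]), Fbn1 (13.6 and 8.47, 0.68 [-0.50, 2.16]) and Lox (15.9 and 11.3, 0.49 [-0.54, 1.74]), Col1a1 (160.2 and 164, -0.03 [-0.31, 0.26]) and Col3a1 (353 and 299, 0.24 [0.03, 0.45]), and Mmp2 (16.9 and 4.24, 1.999 [0.41, 4.30], 3 UMIs in the latter), Mmp3 (15.6 and 14.1, 0.14 [-0.80, 1.24]) and Timp1 (45.2 and 18.4, 1.30 [0.50, 2.22]). Subtracting free RNA left no Col3a1 at day 7.

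**Figure D3:**
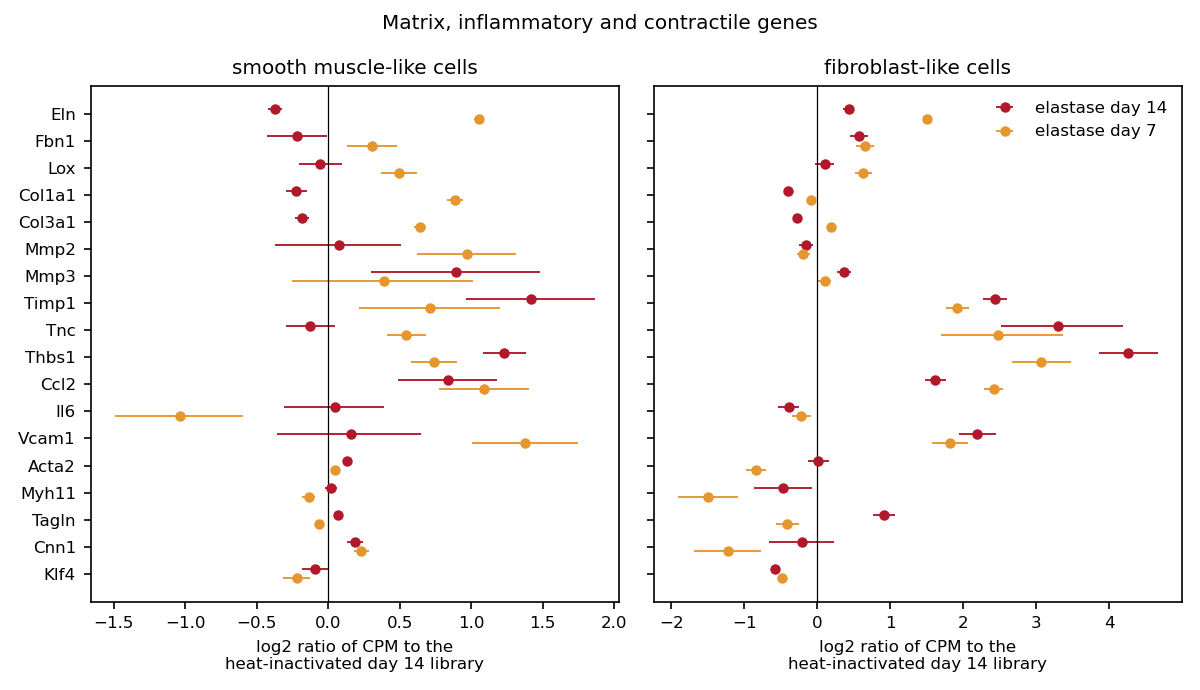
log2 ratio of CPM to the heat-inactivated day 14 library (horizontal axis) for matrix, inflammatory and contractile genes (vertical axis) in smooth muscle-like and fibroblast-like cells of elastase day 14 and elastase day 7 (point colours). Lines are exact 95% intervals of a ratio of 2 counts.

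Elastase day 14 was compared with elastase day 7 in 5 classes, and genes with levels given above are listed with the ratio alone. Interferon response genes were lower at day 14 in T cell-like, dendritic-like, macrophage-monocyte-like and fibroblast-like cells, with none of the measured members higher in the former 3. Fewer macrophage-monocyte-like cells lay in cluster 2 at day 14, and their classical monocyte genes were lower, such as Ly6c2 (3.86-fold lower [3.62, 4.13]). In smooth muscle-like cells, Eln was 2.69-fold lower [2.60, 2.78] at day 14, with lower fibrillar collagen genes and higher immediate early genes.

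Macrophage-monocyte-like cells (609 and 784 cells) had higher Hspa1a (579 and 214, 1.44 [1.35, 1.53]), the sialoglycoprotein Spn (54.1 and 21.1, 1.36 [1.06, 1.67]) and the kinase Map3k14 (55.3 and 22.0, 1.33 [1.04, 1.63]) at day 14. Lower were the monocyte gene Ly6c2 (203 and 784, -1.95 [-2.05, -1.85]), the neutrophil chemokine Cxcl3 (75.8 and 303, -2.001 [-2.16, -1.84]) and Plac8 (274 and 992, -1.86 [-1.94, -1.77]). Cluster 2, which Ly6c2 marked, held 67 of the cells at day 14 and 295 at day 7. Lower groups were classical monocyte (0 of 12, -1.35), interferon response (0 of 23, -0.81), chemokines (4 of 21, -0.38) and inflammatory cytokines and mediators (3 of 17, -0.23). Their members included Isg15 (255 and 602, -1.24 [-1.33, -1.15]) and Cxcl9 (12.2 and 44.2, -1.85 [-2.27, -1.46]). With clusters weighted equally, the classical monocyte median was -0.57 and the interferon response median -0.54.

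Further groups lower in macrophage-monocyte-like cells were alternatively activated macrophage (4 of 14, -0.71), resident macrophage (2 of 14, -0.64), inflammatory macrophage (5 of 14, -0.20), MHC class I (1 of 12, -0.34) and lysosomal cathepsins (3 of 10, -0.24). The direction was the same for unfolded protein response (5 of 18, -0.30), antioxidant response (4 of 16, -0.24) and matrix metalloproteinases (2 of 9, -0.31). Higher groups were proliferation (19 of 22, 0.63), immediate early genes (15 of 19, 0.41), heat shock (8 of 12, 0.29), endothelial lipid uptake (6 of 7, 0.29) and cytosolic ribosomal proteins (22 of 22, 0.15), with the mitotic gene Cenpf (14.0 and 4.27, 1.71 [1.06, 2.39]) and Nr4a1 (200.3 and 94.6, 1.08 [0.94, 1.23]). Genes of interest were Il1b (0.12 [0.05, 0.18]), Ccl2 (-0.12 [-0.16, -0.07]) and Il6 (-0.08 [-0.59, 0.41]), Spp1 (-1.12 [-1.20, -1.04]), Thbs1 (-0.75 [-0.83, -0.67]) and Tgfb1 (0.01 [-0.08, 0.09]), and Mmp9 (-2.53 [-3.04, -2.06]) and Mki67 (0.81 [0.37, 1.25]). Others were Klf4 (-0.02 [-0.12, 0.08]), Vcam1 (-0.82 [-1.23, -0.42]) and Icam1 (0.00420 [-0.19, 0.19]). The strict filter moved Mmp9 to -0.10, and per-cell marker scores turned it to 0.27. Separate clustering of each library turned Vcam1 to 0.18. Equal cell weights turned Il1b to -0.02.

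Aortic wall genes in macrophage-monocyte-like cells lay at 1 to 6% of the highest class. Their groups were contractile apparatus (15 of 21, 0.13, percentile 95.7), fibrillar collagens (0 of 6, -0.38), elastic fibre (6 of 17, -0.25) and matricellular and wound matrix (3 of 15, -0.65). Single genes were Acta2 (0.30 [0.17, 0.43]), Myh11 (0.25 [-0.12, 0.61]), Tagln (0.36 [0.19, 0.53]) and Cnn1 (0.30 [-0.10, 0.70]), Eln (-1.50 [-1.72, -1.28]), Fbn1 (0.04 [-0.43, 0.50]) and Lox (8.23 and 15.9, -0.95 [-1.50, -0.42]), Col1a1 (-0.33 [-0.47, -0.19]) and Col3a1 (-0.63 [-0.74, -0.53]), and Mmp2 (-0.24 [-0.68, 0.20]), Mmp3 (0.16 [-0.26, 0.58]) and Timp1 (-0.92 [-1.23, -0.61]). Subtracting free RNA turned Col3a1 to 4.78 and the elastic fibre median to 0.39.

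Smooth muscle-like cells (256 and 266 cells) had higher Pln (2.17 [1.50, 2.88]), the DNA polymerase subunit gene Pola2 (35.3 and 7.90, 2.16 [1.47, 2.91]) and Nrip2 (33.7 and 8.26, 2.03 [1.34, 2.76]) at day 14. Cluster 17 held 38 and 10 of these cells, and the 3 genes were not compared within clusters. Lower genes were Eln (-1.43 [-1.47, -1.38]), Igfbp2 (51.1 and 156, -1.61 [-1.91, -1.32]) and Dbp (16.6 and 49.5, -1.58 [-2.12, -1.06]). Matrix groups were lower: fibrillar collagens (0 of 5, -0.87), elastic fibre (3 of 17, -0.50), basement membrane (2 of 13, -0.46), collagen processing (1 of 15, -0.26) and matricellular and wound matrix (3 of 14, -0.58). They included Col1a1 (-1.11 [-1.19, -1.04]) and Col3a1 (-0.83 [-0.88, -0.77]), Fbn1 (-0.53 [-0.76, -0.30]), Lox (-0.55 [-0.71, -0.38]) and Tnc (-0.67 [-0.86, -0.49]). Spp1 (9.14 and 24.1, -1.40 [-2.16, -0.68]), Mmp2 (-0.89 [-1.35, -0.45]) and Tgfb1 (-0.44 [-0.79, -0.09]) were lower, at 3.63%, 5.76% and 5.44% of the highest class. Also lower were lysosomal cathepsins (2 of 10, -0.21), leukocyte adhesion molecules (2 of 6, -0.42), integrins (1 of 12, -0.19) and unfolded protein response (4 of 16, -0.15), with Vcam1 (-1.22 [-1.72, -0.74]). The strict filter turned the unfolded protein response median to 0.00390.

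Higher groups in smooth muscle-like cells were immediate early genes (19 of 19, 0.38), heat shock (12 of 12, 0.48), contractile apparatus (16 of 24, 0.09), Notch pathway (8 of 10, 0.37) and cholesterol synthesis (10 of 13, 0.27). Genes among them were Atf3 (2069 and 1072, 0.95 [0.88, 1.02]), Hspa1b (1.22 [1.13, 1.31]) and Nrarp (32.0 and 8.26, 1.95 [1.27, 2.69]), Acta2 (0.09 [0.07, 0.10]), Myh11 (0.16 [0.11, 0.21]) and Tagln (0.13 [0.11, 0.15]), and Cnn1 (-0.04 [-0.10, 0.02]) and Klf4 (0.13 [0.02, 0.24]). Others were TGF-beta pathway (13 of 21, 0.12), endothelial lipid uptake (6 of 7, 0.59), ADAM and ADAMTS proteases (7 of 11, 0.21) and proteoglycans and cartilage matrix (6 of 10, 0.24). Thbs1 (0.49 [0.33, 0.66]) and Timp1 (0.71 [0.22, 1.20], 3.04% of the highest class) were higher, and the strict filter turned Thbs1 to -0.85. Leukocyte groups at 2 to 4% of the highest class were chemokines (5 of 16, -0.28), inflammatory cytokines and mediators (6 of 11, 0.11, percentile 85.7), MHC class II (5 of 6, 0.38), complement (10 of 12, 0.23) and classical monocyte (1 of 9, -0.91). Their genes included Il1b (0.74 [0.24, 1.24]), Il6 (1.08 [0.58, 1.60]) and Ccl2 (-0.25 [-0.60, 0.10]). Without doublet removal the chemokine median was 0.12. Remaining groups were matrix metalloproteinases (2 of 5, -0.02, percentile 53.6) and proliferation (4 of 5, 0.40, percentile 97.3). Clusters weighted equally gave -0.01 for the TGF-beta pathway, and the strict filter turned Klf4 to -0.12.

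Fibroblast-like cells (200 and 286 cells) had a median log2 ratio over all measured genes of 0.12. Higher genes were the Wnt antagonist Frzb (72.1 and 11.9, 2.60 [2.14, 3.08]), the arginine transporter Slc7a2 (159 and 35.5, 2.16 [1.89, 2.44]) and the neurotrophin Bdnf (24.7 and 3.97, 2.64 [1.84, 3.51]). Lower were Cfd (153 and 1270.2, -3.05 [-3.21, -2.90]), Lrg1 (12.99 and 77.4, -2.57 [-3.16, -2.04]) and Hp (218 and 797, -1.87 [-2.01, -1.74]), the last 2 encoding plasma glycoproteins. Per-cell marker scores moved Lrg1 to -0.45 and Hp to -0.80. Lower groups were chemokines (7 of 21, -0.58), interferon response (3 of 23, -0.54), fibrillar collagens (2 of 7, -0.29), unfolded protein response (5 of 18, -0.24) and cytosolic ribosomal proteins (0 of 22, -0.21). Myeloid and lipid groups were classical monocyte (3 of 9, -0.39), lipid-associated macrophage (7 of 16, -0.14) and endothelial lipid uptake (3 of 8, -0.21). Higher groups were basement membrane (8 of 15, 0.37), glycolysis (11 of 15, 0.32), heat shock (12 of 12, 0.29), immediate early genes (15 of 19, 0.15), Notch pathway (7 of 8, 0.54) and angiogenic tip endothelium (6 of 9, 0.99), with the collagen IV gene Col4a1 (489 and 245, 0.99 [0.87, 1.12]). Per-cell marker scores turned the lipid-associated and lipid uptake medians to 0.12 and 0.14.

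Matrix genes of fibroblast-like cells were Eln (-1.08 [-1.13, -1.03]), Fbn1 (-0.09 [-0.17, 0.00310]) and Lox (-0.53 [-0.62, -0.43]), Col1a1 (-0.31 [-0.33, -0.29]) and Col3a1 (-0.48 [-0.49, -0.46]), and Mmp2 (0.04 [-0.04, 0.11]), Mmp3 (0.27 [0.20, 0.34]) and Timp1 (0.52 [0.44, 0.59]). Wound matrix genes were Thbs1 (1.19 [1.08, 1.30]), Tnc (0.82 [0.53, 1.11]) and Spp1 (0.13 [-0.05, 0.30]). Inflammatory genes were Ccl2 (-0.80 [-0.87, -0.73]), Il6 (-0.17 [-0.30, -0.05]) and Il1b (0.43 [0.01, 0.85]), Vcam1 (0.37 [0.25, 0.49]) and Icam1 (0.01 [-0.18, 0.20]), and Tgfb1 (0.60 [0.29, 0.91]) and Klf4 (-0.09 [-0.14, -0.05]). Groups within the range of random lists were elastic fibre (8 of 19, -0.09, percentile 5.43), matrix metalloproteinases (6 of 9, 0.25, percentile 91.0), inflammatory cytokines and mediators (9 of 15, 0.20, percentile 91.0) and proliferation (7 of 12, 0.52, percentile 96.7). Contractile genes were higher (18 of 20, 0.58) at 5.49% of the highest class, with Acta2 (0.86 [0.73, 0.98]), Myh11 (1.03 [0.62, 1.44]), Tagln (1.32 [1.20, 1.44]) and Cnn1 (1.01 [0.58, 1.44]). Equal cell weights turned Klf4 to 0.09.

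T cell-like cells (137 and 164 cells) had higher Calca (241 and 45.0, 2.42 [1.90, 2.97]), which encodes calcitonin gene-related peptide, Snhg12 (145 and 45.0, 1.68 [1.12, 2.27]) and Nr4a1 (384 and 150.2, 1.35 [1.04, 1.68]) at day 14. Per-cell marker scores moved Calca to 0.81. Lower were the interferon-induced genes Cxcl10 (15.5 and 94.7, -2.61 [-3.79, -1.62]), Bst2 (141 and 380.0, -1.43 [-1.80, -1.08]) and Isg15 (86.0 and 202, -1.23 [-1.72, -0.77]). The interferon response group (0 of 18, -1.29) was lower, as were MHC class I (2 of 12, -0.22), proliferation (4 of 16, -0.40), glycolysis (7 of 15, -0.20), classical monocyte (2 of 8, -0.48) and ADAM and ADAMTS proteases (1 of 5, -0.62). Higher groups were immediate early genes (18 of 19, 0.51), heat shock (10 of 12, 0.50) and antioxidant response (12 of 15, 0.39). At 2 to 10% of the highest class lay MHC class II (6 of 6, 1.47), complement (6 of 6, 0.68), inflammatory macrophage (7 of 8, 1.31), lipid-associated macrophage (8 of 11, 0.44) and contractile apparatus (11 of 12, 0.63), and inflammatory cytokines and mediators (4 of 8, 0.66) and chemokines (8 of 14, 0.26, percentile 95.4). The strict filter turned the cytokine median to -0.03. Genes were Ccl2 (126 and 65.8, 0.93 [0.41, 1.46]), Tgfb1 (365 and 445, -0.29 [-0.53, -0.04]) and Klf4 (177 and 162, 0.13 [-0.25, 0.51]), and at 1 to 2% of the highest class Acta2 (208 and 155, 0.43 [0.06, 0.79]), Tagln (119 and 77.4, 0.62 [0.11, 1.12]) and Eln (46.5 and 85.5, -0.88 [-1.57, -0.23]), with Col1a1 (133 and 141, -0.09 [-0.52, 0.33]) and Col3a1 (256 and 315, -0.30 [-0.60, -0.01]). Subtracting free RNA left no Eln or Col3a1 at day 7, and separate clustering turned Tgfb1 to 0.10.

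Dendritic-like cells (86 and 125 cells) had higher Ccl2 (422 and 70.2, 2.59 [2.24, 2.95]), Ccl7 (519 and 134, 1.95 [1.68, 2.22]) and Spp1 (130.4 and 43.1, 1.60 [1.10, 2.10]) at day 14. Lower were Ifit1 (3.56 and 50.7, -3.83 [-6.15, -2.22], 3 UMIs in the former), the tetraspanin Tspan3 (48.6 and 195, -2.01 [-2.52, -1.52]) and Cxcl10 (24.9 and 112, -2.18 [-2.91, -1.51]). Per-cell marker scores moved Ifit1 to -1.52 and Cxcl10 to -0.87, and separate clustering moved Spp1 to 0.13. Lower groups were interferon response (0 of 22, -1.16), MHC class I (0 of 12, -0.32), antioxidant response (3 of 16, -0.33) and chemokines (6 of 14, -0.29), and higher ones immediate early genes (19 of 19, 0.81), heat shock (10 of 12, 0.42), complement (10 of 11, 0.49) and lipid-associated macrophage (8 of 14, 0.21). Without doublet removal, the contractile median (10 of 13, 0.49) was -0.41. Matrix and other groups were elastic fibre (3 of 7, -0.65), fibrillar collagens (1 of 5, -0.33, percentile 5.79), inflammatory cytokines and mediators (5 of 12, -0.17, percentile 14.7) and proliferation (3 of 9, -0.42, percentile 3.83). Genes were Il1b (1276 and 1476, -0.21 [-0.32, -0.10]), Tgfb1 (320.1 and 283, 0.18 [-0.06, 0.41]), Klf4 (192 and 138, 0.48 [0.16, 0.80]) and Icam1 (40.3 and 67.7, -0.75 [-1.37, -0.15]), and at 1 to 6% of the highest class Acta2 (164 and 133, 0.30 [-0.04, 0.64]), Tagln (107 and 73.6, 0.54 [0.09, 0.98]) and Eln (35.6 and 70.2, -0.98 [-1.63, -0.36]), with Col1a1 (119 and 137, -0.21 [-0.58, 0.16]), Col3a1 (234 and 309.6, -0.41 [-0.66, -0.15]) and Timp1 (43.9 and 50.7, -0.21 [-0.84, 0.40]). Subtracting free RNA left no Col3a1 at day 7, and resolution 2 turned Klf4 to -0.02. The subtraction also gave 0.20 for chemokines and -0.01 for lipid-associated genes, against 0.15 and -0.04 at a minimum of 100 UMIs. Per-cell scores turned the chemokine median to 0.03, and equal cell weights the elastic fibre median to 0.01. Tagln was -0.65 without doublet removal.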

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

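The explanations weighed here were chosen after the medians of smooth muscle-, fibroblast- and macrophage-monocyte-like cells had been seen, and the bounds of each test were written before its value. The following 10 results, from the lists and the fixed set of genes, drew attention because elastase day 14 and elastase day 7 lay on opposite sides of the shared heat-inactivated library, with gene intervals that excluded 0 or list medians outside the central 95% of random lists on both days, and the difference between the days was not tested. Other genes, such as Pln with 2.17 in smooth muscle-like cells, were not screened.

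Differences are given as the log2 ratio at day 14 minus that at day 7. In smooth muscle-like cells they were -0.55 for the elastic fibre median, 0.38 for the immediate early median, 0.13 for Tagln, -1.43 for Eln, -0.53 for Fbn1, -1.11 for Col1a1 and -0.83 for Col3a1. In fibroblast-like cells they were 1.32 for Tagln and -0.48 for Col3a1, and in macrophage-monocyte-like cells -0.63 for Col3a1. With the strict filter, Fbn1 and Tagln at day 14 and the immediate early median at day 7 changed sign in smooth muscle-like cells (0.10, -0.07 and 0.03). Subtracting free RNA left no day 7 Col3a1 in macrophage-monocyte-like cells and no heat-inactivated Tagln in fibroblast-like cells.

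Heat shock genes were higher at elastase day 14 than in the heat-inactivated library in smooth muscle-like cells. Handling of whole libraries could account for a part, since the lowest of the B cell-, T cell- and endothelial-like medians was 0.47 (B cell-like 0.72, T cell-like 0.69). For a response of wall cells, the lower of the smooth muscle- and fibroblast-like medians exceeded the higher lymphocyte median by 0.56, with a counting range that reached below the bound of 0.5, while endothelial-like cells, also of the wall, had the lowest median. A mix of smooth muscle-like clusters is argued against by the median of 1.31 [1.22, 1.38] with clusters weighted equally. Handling and a response to active elastase stay open together, because each group is 1 library.

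Interferon response genes were lower at day 14 than at day 7 in T cell-like cells. Free RNA is argued against: smooth muscle-like cells, with the fewest interferon list UMIs per cell of 6 classes at day 7 (2.52), held 41.4% [36.7, 46.7] of the drop per T cell-like cell (6.09). A mix of T cell-like clusters is argued against by the median of -1.31 [-1.64, -1.12] with clusters 8 and 12 weighted equally. A difference between days could not be told from one between the 2 pools.

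Fibrillar collagen genes were higher in smooth muscle-like cells at elastase day 7 than in the heat-inactivated library. RNA or cells of fibroblasts are argued against: at the level of the fibroblast marker Cygb (8 UMIs), they would give a median of 7.98% [3.44, 15.8] of the collagen UMIs of these cells, and at that of Dcn (220 UMIs) 10.6% [9.22, 12.1]. A mix of smooth muscle-like clusters is argued against by the median of 0.72 [0.61, 0.74] with clusters 0 and 3 weighted equally. Treatment and day differ together in this comparison and could not be separated.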

How the results depend on the processing

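Of the alternatives, leaving erythroid-like cells out of the denominator, or immediate early and heat shock genes out of the totals, and weighting clusters equally were chosen after the data were seen. With 1 pooled library per group, no paired analysis or test was possible. A value counts as moved when it left its counting interval or range, and as reversed when it took the other sign although that interval had excluded 0 (for a list, when its median lay outside the central 95% of random lists). For 284 gene ratios, 3395 alternative values were computed, of which 3022 stayed, 340 moved and 33 reversed. The 233 list medians gave 3396 values (2967, 378 and 51), and the 33 unsigned shares gave 294 (254 and 40). In these counts, clusters were weighted equally only for smooth muscle-, fibroblast- and macrophage-monocyte-like cells, in clusters with at least 20 cells in both libraries. Lists left with under 5 measured genes, genes with no counts to compare, and erythroid-like shares without erythroid-like cells gave no value. Directions were kept in 3287 gene and 3302 list values. Values that reversed, or moved for a main result, are given, and the cause was not tested.

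With the strict filter, shares were B cell 5.64%, T cell 4.11%, dendritic 2.35%, endothelial 7.76%, erythroid 0%, fibroblast 32.0%, macrophage-monocyte 16.5% and smooth muscle 27.6% in the heat-inactivated library. Macrophage-monocyte and smooth muscle were 49.2% and 5.83% in elastase day 7 and 48.7% and 9.83% in elastase day 14, with erythroid 0% in both. Separate clustering gave B cell 6.15%, NK cell 0% and dendritic 0% in the heat-inactivated library, and NK cell 0% in elastase day 14. Separate clustering and Leiden resolution 0.5 gave lymphatic endothelial 0% in each library, and the latter dendritic 2.03% in the heat-inactivated library. With the lenient filter, shares were erythroid 10.3% in the heat-inactivated library, erythroid 2.13% in elastase day 7, and erythroid 3.36% and lymphatic endothelial 0% in elastase day 14. With per-cell marker scores, shares were macrophage-monocyte 7.68% and smooth muscle 45.2% in the heat-inactivated library. They were NK cell 6.72%, T cell 6.88%, lymphatic endothelial 0.392% and macrophage-monocyte 34.1% in elastase day 7, and NK cell 2.32%, T cell 7.82%, dendritic 4.37% and macrophage-monocyte 33.6% in elastase day 14. Scrublet's automatic threshold gave T cell 7.82% in elastase day 14.

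The next values belong to elastase day 14 against the heat-inactivated library. Subtracting free RNA gave Ccl21a 1.35, Ccl2 -0.30, interferon response -0.026 and MHC class I -0.33 in smooth muscle-like cells, and Myh11 3.47 in fibroblast-like cells. The strict filter gave Acta2 -0.016, Tagln -0.067, Fbn1 0.099, contractile apparatus -0.073 and heat shock 1.64 in smooth muscle-like cells, and proliferation 2.78 in macrophage-monocyte-like cells. Weighting clusters equally gave heat shock 1.31 and Notch pathway -0.064 in smooth muscle-like cells. In macrophage-monocyte-like cells it gave matricellular and wound matrix 0.0075, lysosomal cathepsins 0.14, resident macrophage -0.35, lipid-associated macrophage 0.087, proliferation -0.0068 and cell death genes -0.0011. In fibroblast-like cells it gave chemokines 0.90 and leukocyte adhesion molecules -0.29. Leiden resolution 0.5 and separate clustering gave resident macrophage -2.97 and -3.000, and proliferation 2.59 and 2.64, in macrophage-monocyte-like cells. Weighting each cell equally gave proliferation 1.12 in macrophage-monocyte-like cells, and Mmp3 -0.064 and chemokines 1.53 in fibroblast-like cells. List minimums of 1 and 100 UMIs gave proliferation 1.27 and 1.34 in macrophage-monocyte-like cells. In fibroblast-like cells the former gave chemokines 1.54 and the latter lipid-associated macrophage -0.10. Per-cell marker scores gave chemokines 1.60 in fibroblast-like cells.

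For elastase day 7 against the heat-inactivated library, values were as follows. Subtracting free RNA gave Timp1 -0.17, Ccl2 -0.61, fibrillar collagens 0.86, proteoglycans and cartilage matrix 0.14, inflammatory cytokines and mediators -0.34, interferon response -0.29 and MHC class I -0.29 in smooth muscle-like cells. In macrophage-monocyte-like cells it gave Col3a1 -6.84. In fibroblast-like cells it gave Acta2 5.61, Myh11 0.65, Tagln 5.83, Cnn1 0.042, contractile apparatus 0.43 and complement -0.12. The strict filter gave Acta2 -0.091, Il6 0.11, Klf4 0.22, contractile apparatus -0.15, fibrillar collagens 0.91, proteoglycans and cartilage matrix 0.28 and immediate early genes 0.026 in smooth muscle-like cells. Weighting clusters equally gave fibrillar collagens 0.72 in smooth muscle-like cells. In macrophage-monocyte-like cells it gave interferon response 0.74, resident macrophage -0.16, lipid-associated macrophage 0.37 and proliferation -0.28, and chemokines 1.30 in fibroblast-like cells. Leiden resolution 0.5 and separate clustering gave resident macrophage -2.30 and -2.32 in macrophage-monocyte-like cells. Weighting each cell equally gave contractile apparatus -0.056 and fibrillar collagens 0.66 in smooth muscle-like cells, and Mmp3 -0.13 and chemokines 1.89 in fibroblast-like cells. A list minimum of 1 UMI gave angiogenic tip endothelium -0.25 in smooth muscle-like cells, and leukocyte adhesion molecules -0.43 in fibroblast-like cells. A list minimum of 100 UMIs gave proteoglycans and cartilage matrix 0.063 and inflammatory cytokines and mediators -0.10 in smooth muscle-like cells. Keeping doublets and Scrublet's automatic threshold gave contractile apparatus -0.11 and -0.12 in smooth muscle-like cells, and proliferation -0.042 and -0.038 in fibroblast-like cells. In the latter cells, median-of-ratios scaling gave Col1a1 0.0032 and chemokines 2.51, the lenient filter proliferation -0.017, and per-cell marker scores lipid-associated macrophage -0.33.

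The last values belong to elastase day 14 against elastase day 7. Subtracting free RNA gave Col3a1 4.78 and elastic fibre 0.39 in macrophage-monocyte-like cells, and chemokines 0.051 in smooth muscle-like cells, and Eln 1.49 and Col3a1 3.58 in T cell-like cells. In dendritic-like cells it gave Col3a1 2.88, chemokines 0.20 and lipid-associated macrophage -0.012. The strict filter gave Thbs1 -0.85, Klf4 -0.12, elastic fibre -0.59, chemokines 0.11 and unfolded protein response 0.0039 in smooth muscle-like cells, and lipid-associated macrophage 0.0021 and endothelial lipid uptake 0.0047 in fibroblast-like cells. In T cell-like cells it gave inflammatory cytokines and mediators -0.025. Weighting clusters equally gave interferon response -0.54 and classical monocyte -0.57 in macrophage-monocyte-like cells. In smooth muscle-like cells it gave fibrillar collagens -0.70, elastic fibre -0.35 and TGF-beta pathway -0.0062, and endothelial lipid uptake 0.15 in fibroblast-like cells. Separate clustering gave Vcam1 0.18 in macrophage-monocyte-like cells, and Tgfb1 0.098 in T cell-like cells. Weighting each cell equally gave Il1b -0.021 and classical monocyte -1.59 in macrophage-monocyte-like cells, and fibrillar collagens -0.79 in smooth muscle-like cells, and Klf4 0.095 in fibroblast-like cells. In dendritic-like cells it gave elastic fibre 0.0060. A list minimum of 1 UMI gave endothelial lipid uptake 0.30 in fibroblast-like cells. A list minimum of 100 UMIs gave chemokines 0.15 and lipid-associated macrophage -0.043 in dendritic-like cells. Per-cell marker scores gave Mmp9 0.27 in macrophage-monocyte-like cells, and fibrillar collagens -0.79 in smooth muscle-like cells, and lipid-associated macrophage 0.12 and endothelial lipid uptake 0.14 in fibroblast-like cells. In dendritic-like cells it gave chemokines 0.030. Keeping doublets and Scrublet's automatic threshold gave chemokines 0.12 and 0.0093 in smooth muscle-like cells. In dendritic-like cells they gave Tagln -0.65 and -0.22, and contractile apparatus -0.41 and -0.14. The threshold gave inflammatory cytokines and mediators -0.035 in T cell-like cells. Leiden resolution 2 gave Klf4 -0.015 in dendritic-like cells.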

Other observations

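These genes and groups, from classes of 20 to 49 cells in at least 1 library (below the minimum above), were picked after their values had been seen. In endothelial-like cells of elastase day 14 (34 cells) against the heat-inactivated library (77 cells), the monocyte chemokine Ccl2 (672 and 32.2, 4.39 [3.72, 5.13]) and Hspa1b (661 and 246, 1.43 [1.11, 1.75]) were higher and the alcohol dehydrogenase Adh7 (18.6 and 162, -3.13 [-4.78, -1.86]) lower. In B cell-like cells (34 and 55 cells), Hsp90ab1 (1086 and 562, 0.95 [0.56, 1.34]) was higher and Cd2 (118 and 395, -1.74 [-2.66, -0.92]) lower. In T cell-like cells (137 and 43 cells), interferon response (6 of 8, 1.14) was higher and Rgcc (222 and 489, -1.14 [-1.57, -0.70]) lower. At 3 to 5% of the highest class, MHC class II (6 of 6, 2.80) and complement (5 of 6, 1.74) were higher and contractile apparatus (0 of 9, -1.30) lower, the last also in B cell-like cells (0 of 7, -1.33).

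Of the barcodes below the minimum of 300 detected genes, 167 in the heat-inactivated library (10.0% [8.62, 11.6] of all its barcodes), 71 at elastase day 7 (3.72% [2.91, 4.66]) and 48 at elastase day 14 (3.19% [2.36, 4.21]) held mostly haemoglobin UMIs.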
